A study of Arabidopsis thaliana with 12 samples.

How the data were processed

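RNA sequencing of Arabidopsis thaliana seedlings was analysed in 12 libraries from 4 genotypes, with 3 libraries in each. The genotypes were the wild type Col, 2 lines labelled as an H3.3 knockout that carries a mutated copy of the H3.3 gene HTR5 (T31A and K36A), and the mutant efs. EFS, also known as SDG8, is a histone methyltransferase that acts on lysine 36 of histone H3. Per the labels' protocols, seedlings were grown for 10 days at 22 °C with 16 h of light and 8 h of dark, and libraries were made from total RNA with an NEBNext Ultra RNA kit. Group and replicate number of each library were taken from its title. The labels do not say whether the 3 libraries of a genotype came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. They give no time of harvest and no library batch, and do not say whether strand was kept.

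Per the submitters' processing notes, the tools used were fastp 0.20.1, HISAT2 2.1.10 and DESeq2 1.26.0, with the build TAIR10; which tool counted reads is not given in the sources used here. The deposited table holds 1 TPM value (scaled by gene length and library size) for each of 23916 genes in each of the 12 libraries. The authors named its columns as gene counts, but the 12 columns share one sum and most values are not whole, so they were treated as TPM. In each gene, the 12 values were whole multiples of a common unit once each library's scale was set, within a tolerance of 0.001. This held for 100.0% of the genes, although it is easily met, and so shows little, where a gene has few different values above 0. It gave back whole reads up to a factor shared by the 12 libraries. In 202 genes such a factor was restored from the span of the gene. For the 171 locus codes not found in the reference no span was at hand to check it. The recovered total per library was 17625043 to 34108698 reads. The gene length in the TPM was the span of the gene with its introns: among 12466 genes with at least 3000 reads, 99.98% had a recovered length within 1 percent of the span. When the comparison was made with the longest transcript, on 12474 genes, the share was 3.03%. TPM levels of genes with long introns are therefore low next to those of genes without introns. Ratios of TPM between libraries within 1 gene are not touched by this, but the filter and the log2(TPM + 1) scale below are, since a lower TPM shrinks the log2 difference.

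The reference used here was TAIR10.1, for gene names, gene and transcript lengths, GC content, neighbours and process terms, and no coordinates were taken from it. Of the listed locus codes, 23745 were found in it and 171 were not. The reference has 27550 protein-coding genes, of which 3817 are outside the table and were not analysed here. Among them were 5 members of the gene lists, SPL5, PDF1.2, MYC2, LEC1 and SMR5. Another 4 members, HSP70-4, HSP22, HSP23.6 and IPMDH1, were left out because the reference gives their locus codes another symbol. Genes that overlap another annotated gene or have a near-identical copy are uncertain, since the counting of shared reads and of strand is not stated.

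Genes with a TPM of at least 1 in at least 3 of the 12 libraries were tested, 19984 in all. Log2(TPM + 1) was fitted with limma (version 3.58.1, R 4.3.3) over the 12 libraries and 4 groups, without a term for the replicate number, with a mean-dependent prior variance. Each contrast had a two-sided moderated test with Benjamini-Hochberg adjustment over the 19984 genes, and a gene was called at an adjusted p under 0.05. Log2 differences are on the log2(TPM + 1) scale, which understates the change of genes with low TPM. All 6 contrasts of the 4 genotypes came from 1 fit.

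A total of 23 gene lists and the rule for named genes were fixed before the data were examined. The named genes are EFS and the 3 H3.3 genes, the FLC clade, the 8 largest rises and 8 largest falls against Col, the 5 largest in each direction between mutants, and up to 4 members of each list with the smallest p, or 2 where none was called. Largest changes were taken among called protein-coding genes with a mean TPM of at least 5 whose 3 libraries of one group all lay on one side of those of the other. Other genes named by value are members of the lists or neighbours of HTR5, and 1 gene that the rule names is not reported here. Lists were tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over the 23 lists, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move, on balance, one way, and compares them with no other genes. Counts adjusted over the list alone used the same p-values with the adjustment restricted to the tested members.

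Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, no filter on low values and a mean TPM of at least 5, and a fold of at least 2 besides the adjusted p. Further ones were nuclear genes only, median-of-ratios factors, quantile normalization, a robust prior, a fit of only the 2 groups compared, a replicate block, and leaving out each library in turn. Chosen after seeing the data were voom (limma) on the recovered reads, removal of each library's trend over transcript length and GC content (a spline with 5 degrees of freedom, for the 99.4% of tested genes with both values), and the fits without Col replicate 1 as a library of its own kind. For overlaps between comparisons that share the Col libraries, 100 simulations of unchanged groups gave the values for no effect. The fit was tested on simulated data for the contrast of T31A and Col, with 200 of 19984 genes changed. It recovered 0% of genes changed by 1.25-fold. Of those changed by 1.5-fold it recovered 55.5%, with 5.1% of the calls on unchanged genes. Of those changed by 2-fold it recovered 91.5%, with 4.2% of the calls on unchanged genes. In the real data, 26.8% of tested genes were called in this contrast, and the adjustment is less strict where more genes change. The simulated reads also had the same dispersion in every gene, while the spread of real genes was not used. The simulated shares therefore give neither the recovery nor the share of false calls in the real data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.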

Results

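Transcript levels were measured in 10-day-old Arabidopsis seedlings of 4 genotypes, to ask how a residue that sets histone H3.3 apart from H3.1, and the lysine on H3.3 that carries H3K36 methylation, act on gene expression. Col is the wild type. T31A plants are labelled as an H3.3 knockout that carries an HTR5 copy with alanine for the threonine found in H3.3 and not in H3.1. K36A plants carry the same kind of copy with alanine for the methylated lysine, and efs plants are mutated in the methyltransferase EFS. No library of the H3.3 knockout with an unmutated HTR5 copy was analysed here, so a difference between T31A or K36A and Col covers the labelled knockout, the added copy and the substitution together. Each genotype had 3 libraries, and values are mean TPM ± SD with n = 3 unless stated. The recovered reads numbered 24862203, 25541111 and 19564866 in Col, 34108698, 22340565 and 21027008 in T31A, 23624757, 19403151 and 18595347 in K36A, and 20277597, 17625043 and 18422971 in efs. Across genes, log2(TPM + 1) of libraries of 1 genotype correlated at 0.9859 to 0.9943 in Col and at 0.9896 to 0.9952 in the mutants. Col replicate 1 stood apart in 1 respect, with short transcripts 0.299 log2 units lower against long ones than the average library, where the other 11 libraries lay between −0.051 and 0.159.

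The genes that define the genotypes were read first. HTR8 (AT5G10980), an H3.3 gene, was at 129.7 ± 19.8 TPM in Col, 16.5 ± 3.52 in T31A, 20.7 ± 2.31 in K36A and 219 ± 4.98 in efs. HTR5 (AT4G40040) was at 329 ± 40.7 in Col and rose to 653 ± 25.1 in T31A and 591 ± 3.26 in K36A, where native and added copies cannot be told apart. HTR4 (AT4G40030), the remaining H3.3 gene, fell from 276 ± 37.4 to 192 ± 9.05 and 167 ± 10.7 and was at 262 ± 6.92 in efs. Much of the HTR4 signal thus remained in T31A and K36A, so its level does not by itself show the labelled knockout. The log2 differences from Col in T31A were -2.91 (SE 0.14, adjusted p = 3.2e-09) for HTR8, 0.99 (SE 0.08, adjusted p = 4.4e-07) for HTR5 and -0.51 (SE 0.09, adjusted p = 5.7e-04) for HTR4. Those in K36A were -2.58 (SE 0.14, adjusted p = 2.9e-08), 0.85 (SE 0.08, adjusted p = 3.1e-06) and -0.72 (SE 0.09, adjusted p = 3.7e-05). In efs, HTR8 rose by 0.77 (SE 0.14, adjusted p = 4.0e-04), and HTR5 by 0.27 (SE 0.08, adjusted p = 0.0112), a call that was lost with median-of-ratios factors (adjusted p = 0.191). EFS (AT1G77300) itself was at 15.6 ± 1.91 in Col, 17.8 ± 2.9 in T31A, 17 ± 2.18 in K36A and 15.4 ± 1.04 in efs and was called in no comparison with Col. The labels do not give the lesion in efs, EFS overlaps the gene AT1G77290, and its level checked no label, so directions below are for libraries labelled efs. As a list of 4, these genes rose in 1 and fell in 2 in T31A and in K36A, and rose in 2 in efs. The counts adjusted over the list alone were 3, 3 and 2, and the list as a whole was not called (adjusted p = 0.367, 0.109 and 0.65). H3.3 genes are close copies of each other, and how shared reads were assigned is not stated.

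**Figure D1:**
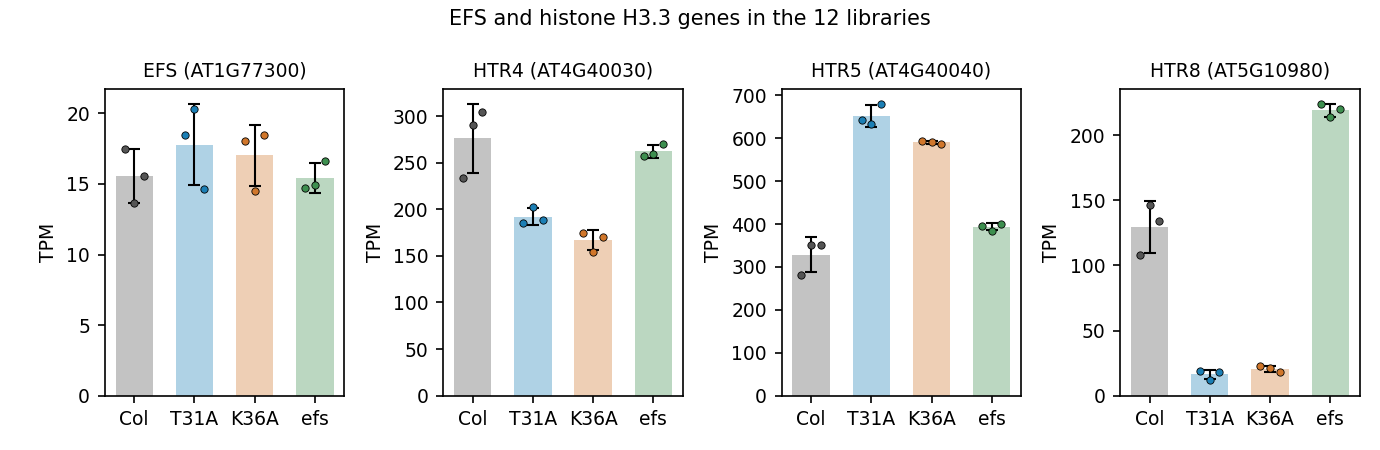
TPM of EFS and the H3.3 genes HTR4, HTR5 and HTR8 (y axis, linear from 0, own scale per gene) in Col, T31A, K36A and efs. Points are the 3 libraries, bars the mean and error bars the SD. HTR8 lies near 16.5 TPM in T31A and 20.7 TPM in K36A against 130 in Col, and EFS overlaps between genotypes.

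FLC, a MADS-box repressor of flowering, and several of its relatives were lower in the mutants than in Col. FLC (AT5G10140) was at 4.75 ± 0.347 TPM in Col and fell to 1.17 ± 0.031 in T31A, 0.643 ± 0.0698 in K36A and 0.262 ± 0.0726 in efs. MAF1 (AT1G77080) fell from 14.9 ± 0.733 to 1.41 ± 0.168 in K36A and 1.18 ± 0.109 in efs, and to 12 ± 0.379 in T31A, a small change whose call was lost without any of 5 of the 6 libraries. Its adjusted p was 0.0308 with all libraries, 0.0655 without Col replicate 1, 0.0886 without Col replicate 2, and 0.0658, 0.104 and 0.0748 without T31A replicates 1, 2 and 3. MAF4 (AT5G65070) and MAF5 (AT5G65080) fell in all 3 mutants, with log2 differences of -0.53 (SE 0.11), -0.91 (SE 0.11) and -1.18 (SE 0.11) for MAF4 and -0.55 (SE 0.15), -0.82 (SE 0.15) and -1.04 (SE 0.15) for MAF5, in the order T31A, K36A and efs. The MAF5 call in T31A (adjusted p = 0.0153) was lost without Col replicate 1 (0.0596) or T31A replicate 3 (0.0534). MAF2 (AT5G65050) and MAF3 (AT5G65060) fell in K36A, to 11.3 ± 0.836 from 22.8 ± 2.28 and to 2.68 ± 0.237 from 6.12 ± 0.336. In T31A and efs, MAF2 stood at 21.6 ± 0.592 and 20.8 ± 1.44 and MAF3 at 7.83 ± 0.336 and 6.83 ± 1.14. The direct contrasts were called as well: T31A minus K36A was 0.88 (SE 0.09, adjusted p = 4.6e-06) for MAF2 and 1.27 (SE 0.11, adjusted p = 1.6e-06) for MAF3, and K36A minus efs was -0.82 (SE 0.09, adjusted p = 3.5e-06) and -1.08 (SE 0.11, adjusted p = 2.6e-06).

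Of the 6 genes of the clade, 4 fell in T31A, 6 in K36A and 4 in efs. Adjusted over the list alone, 5 were called in T31A (MAF3 higher and 4 lower), 6 in K36A and 4 in efs. As a list, they were lower than other genes in each mutant (camera adjusted p = 0.0109, 4.0e-11 and 2.6e-04). In K36A the call held with an estimated correlation (adjusted p = 0.02), and in T31A and efs it was lost (adjusted p = 0.184 and 0.112 with an estimated correlation). In T31A it was also lost with the trend over length and GC content removed (adjusted p = 0.0604). FLC overlaps the annotated gene AT5G01675, and MAF2 to MAF5 are similar neighbours, and how shared reads were assigned is not stated.

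**Figure D2:**
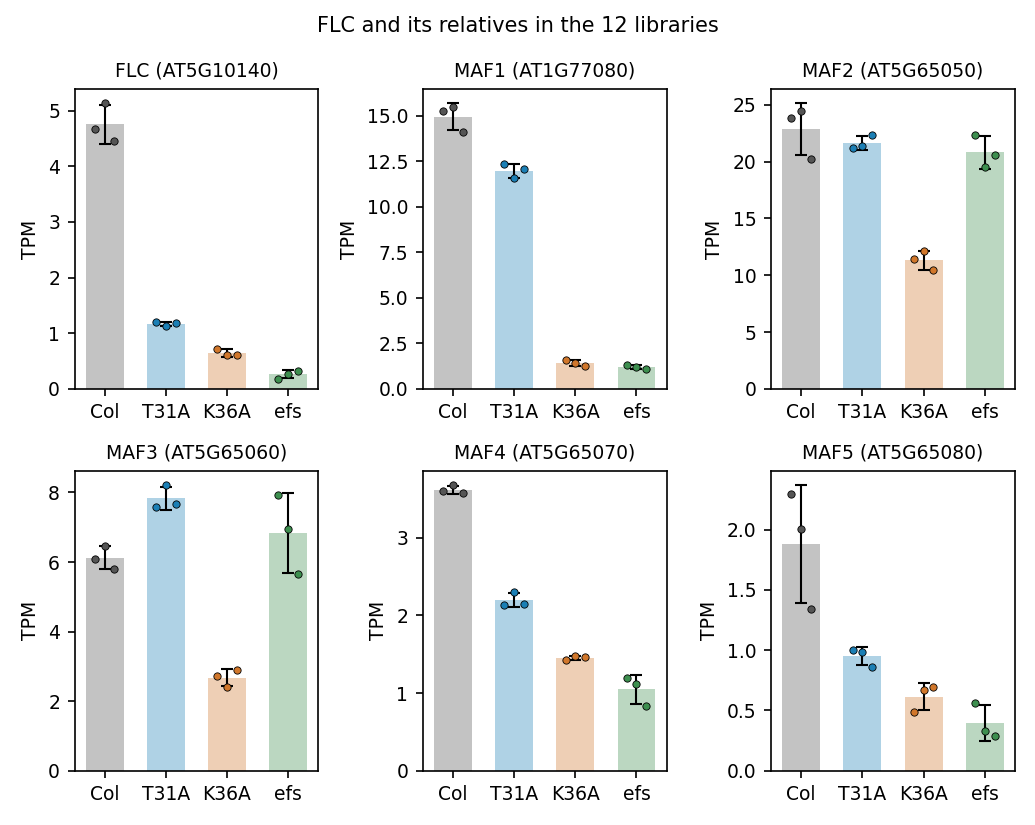
TPM of FLC and MAF1 to MAF5 (y axis, linear from 0, own scale per gene) in Col, T31A, K36A and efs. Points are the 3 libraries, bars the mean and error bars the SD. FLC falls from 4.75 in Col to 1.17, 0.643 and 0.262 in T31A, K36A and efs, and MAF2 and MAF3 are lowest in K36A.

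In T31A seedlings, the largest rises included genes of seed storage proteins and of cytochromes P450, and the largest falls included HTR8 and several uncharacterized genes. SESA5 (AT5G54740), a seed storage albumin, was at 25.2 ± 2.28 TPM against 0.0346 ± 0.060 in Col, and the cruciferins CRC (AT4G28520) and CRA1 (AT5G44120) were at 19.8 ± 1.95 and 18.3 ± 2.05 against 0.306 ± 0.309 and 1.48 ± 0.394. PHI-1 (AT1G35140), a phosphate-induced family member, rose from 3.59 ± 0.608 to 111 ± 4.64 (log2 difference 4.61 (SE 0.09, adjusted p = 4.5e-13)). The cytochromes P450 CYP71A12 (AT2G30750) and CYP81F2 (AT5G57220), which act in the synthesis of indolic defence compounds, rose to 41.6 ± 1.03 from 2.79 ± 0.123 and to 20.4 ± 0.654 from 1.98 ± 0.398. The germin-like GLP9 (AT4G14630) and the peroxidase PER4 (AT1G14540) rose to 29.2 ± 1.16 and 25.9 ± 0.671 from 1.49 ± 0.423 and 2.38 ± 0.51. Among the largest falls besides HTR8 were AT1G75945 (25.9 ± 3.95 to 0.638 ± 0.0435), AT2G15020 (50.6 ± 11.5 to 3.49 ± 0.672) and AT2G24945 (18.5 ± 2.29 to 2.62 ± 0.137), which are uncharacterized. The receptor-like protein RLP19 (AT2G15080), the cytochrome P450 AT3G44970 and AT5G54585 fell too, with log2 differences of -2.56 (SE 0.15), -2.32 (SE 0.12) and -2.00 (SE 0.14). MBF1C (AT3G24500), a heat-related coactivator that overlaps 3 other annotated genes, had a log2 difference of -1.93 (SE 0.10, adjusted p = 7.1e-09).

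Of 19984 genes, 5347 were called between T31A and Col, 3128 higher and 2219 lower in T31A, and 401 of them differed by at least 2-fold (232 higher and 169 lower). Of the called genes, 58.5% were higher with TPM as deposited, 44.6% with median-of-ratios factors and 47.3% with quantile normalization, so the balance of rises and falls depended on the scaling. Without Col replicate 1, 5668 genes were called, 4501 of them among the 5347, and 64.9% were higher.

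In K36A seedlings, the largest rises included the genes of a linker histone and of 2 late embryogenesis proteins, and the largest falls those of a carotenoid isomerase and of MAF1. HIS1-3 (AT2G18050), the drought-induced linker histone H1, rose from 109.6 ± 10.2 to 522 ± 7.4 TPM (log2 difference 2.24 (SE 0.08, adjusted p = 2.9e-10)). EM1 (AT3G51810), a late embryogenesis protein, rose from 1.48 ± 0.699 to 14 ± 2.35, and AT3G02480 of a related family from 11.9 ± 3.27 to 55.9 ± 4.28. PHI-1 rose to 23.5 ± 2.18, the glycine-rich AT2G05510 to 24.7 ± 2.44 from 4.58 ± 0.403, and the uncharacterized AT3G01345 and AT4G19430 to 13.3 ± 2.52 and 13.5 ± 0.984 from 1.52 ± 0.208 and 1.7 ± 0.309. The largest rise was in AT2G05915 (2.84 ± 2.32 to 41.7 ± 3.4), which overlaps AT2G05914. CRTISO (AT1G06820), the carotenoid isomerase, fell from 33.5 ± 0.71 to 4.43 ± 0.0302 (log2 difference -2.67 (SE 0.07, adjusted p = 1.9e-11)). The cystatin-like AT5G05060 fell from 80.7 ± 5.17 to 6.82 ± 0.435, AT1G75945 to 1.77 ± 0.384 and AT2G15020 to 9.64 ± 0.44. AT5G60030 and AT4G01390, which overlap other annotated genes, had log2 differences of -2.56 (SE 0.15) and -2.31 (SE 0.11), and MAF1 and HTR8 were the remaining large falls.

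Between K36A and Col, 6296 genes were called, 4517 higher and 1779 lower in K36A, and 405 differed by at least 2-fold (274 higher and 131 lower). The share of higher calls was 71.7% with TPM as deposited, 47.7% with median-of-ratios factors and 46.9% with quantile normalization. Fitted on the 6 libraries of these groups alone, 4137 genes were called. Without Col replicate 1, 7301 were called, 5533 of them among the 6296, and 76.2% were higher.

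In the libraries labelled efs, the largest rises included 2 xyloglucan endotransglucosylase genes, a myo-inositol oxygenase gene and a proline dehydrogenase gene, and the largest falls included the carotenoid isomerase gene. PHI-1 rose from 3.59 ± 0.608 to 305 ± 11.2 TPM, its relative EXO (AT4G08950) from 69.5 ± 24.2 to 699 ± 61.7, and the xyloglucan endotransglucosylases TCH4 (AT5G57560) and XTR6 (AT4G25810) from 34.5 ± 5.2 to 723 ± 30.7 and from 6.48 ± 0.766 to 96.5 ± 6.7. MIOX2 (AT2G19800), a myo-inositol oxygenase, rose from 5.93 ± 1.55 to 218 ± 8.88, and ERD5 (AT3G30775), the proline dehydrogenase, from 32.9 ± 9.69 to 545 ± 43.1. The transcription factor DREB26 (AT1G21910) rose to 75.5 ± 0.355 from 6.2 ± 1.89, and CRA1 to 38.3 ± 1.73. CRTISO fell to 1.65 ± 0.0735 from 33.5 ± 0.71 (log2 difference -3.70 (SE 0.07, adjusted p = 1.2e-13)), AT2G15020 to 1.16 ± 0.449, AT5G05060 to 8.61 ± 0.381 and AT2G24945 to 1.28 ± 0.221. The F-box gene AT5G56380, AT2G19650 and AT3G44450 had log2 differences of -2.98 (SE 0.14), -2.98 (SE 0.13) and -2.91 (SE 0.18). AT2G15029, which overlaps AT2G15030, was listed at 0 in the 3 efs libraries and at 17.1 ± 4.62 TPM in Col.

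Between efs and Col, 9746 genes were called, 6275 higher and 3471 lower in efs, and 1197 differed by at least 2-fold (578 higher and 619 lower). The share of higher calls was 64.4% with TPM as deposited, 47.9% with median-of-ratios factors and 51.1% with quantile normalization. Without Col replicate 1, 10336 genes were called, 8835 of them among the 9746, and 67.7% were higher.

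**Figure D3:**
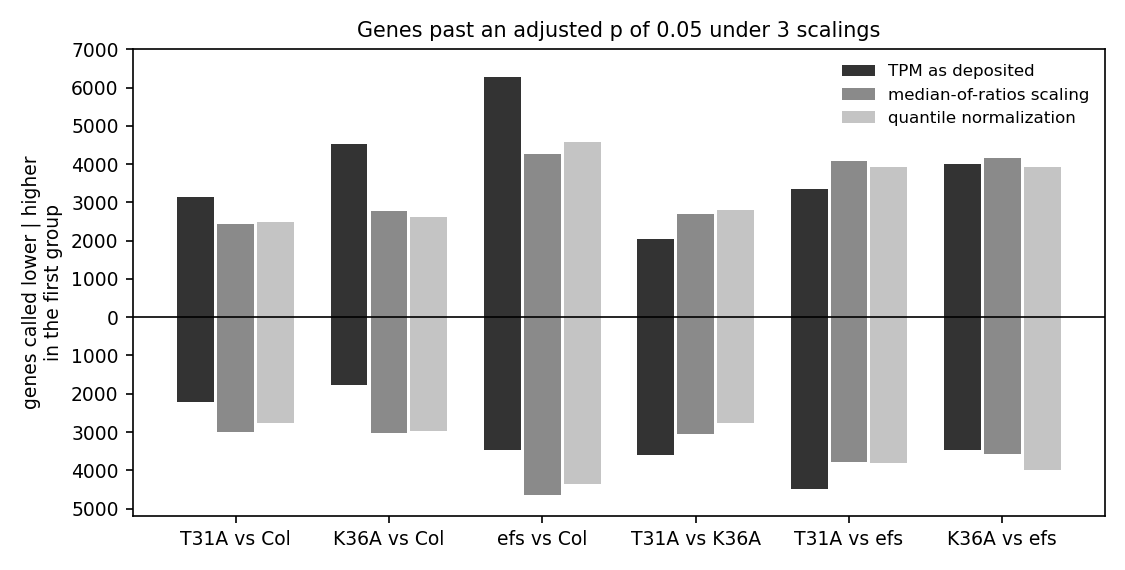
Genes past an adjusted p of 0.05 (y axis, number of genes, higher in the first-named group above 0 and lower below 0) in the 6 comparisons of genotypes, with TPM as deposited, median-of-ratios scaling and quantile normalization. Against Col, the bars above 0 reach 3128, 4517 and 6275 genes with TPM as deposited, and the bars on both sides are closer to equal under the other scalings.

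Genes of aliphatic glucosinolate synthesis, the pathway to methionine-derived defence compounds, fell together in all 3 mutants. Of 13 tested genes, 11 fell in T31A, 13 in K36A and 12 in efs, and none rose. Adjusted over the list alone, 12, 13 and 12 were called. The regulators MYB28 (AT5G61420) and MYB29 (AT5G07690) were at 97.8 ± 16.6 and 39 ± 6.69 TPM in Col, 56.3 ± 1.68 and 12.4 ± 1.41 in T31A, 63.5 ± 2.53 and 12.6 ± 0.807 in K36A, and 34.6 ± 1.95 and 4.64 ± 0.427 in efs. CYP79F1 (AT1G16410), an enzyme of the core pathway, fell from 97.7 ± 8.01 to 36.4 ± 0.367, 41.2 ± 0.166 and 14.5 ± 1.06, and BCAT4 (AT3G19710) of methionine chain elongation from 95.9 ± 6.49 to 34.5 ± 1.55, 36 ± 1.73 and 20.0 ± 1.35. By camera, the adjusted p was 8.2e-15 in T31A, 2.9e-18 in K36A and 2.8e-15 in efs. In T31A and efs the call was lost, with adjusted p = 0.051 and 0.0709 with an estimated correlation, and in K36A it held at 0.0361. CYP79F1 and CYP79F2 are close copies.

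Transcripts that peak in the morning fell and several that peak in the evening rose. Of 9 morning clock genes, 9 fell in T31A, 5 in K36A and 8 in efs (adjusted over the list alone 9, 5 and 8, and camera adjusted p = 1.2e-11, 1.1e-04 and 6.1e-07). CCA1 (AT2G46830) fell from 13 ± 0.177 to 4.81 ± 0.192, 10.4 ± 0.226 and 5.64 ± 0.306, PRR9 (AT2G46790) from 9.67 ± 2.69 to 2.09 ± 0.376, 5.1 ± 0.907 and 0.608 ± 0.161, and LNK1 (AT5G64170) from 47.2 ± 2.24 to 19.8 ± 1.54, 35.3 ± 0.986 and 9.47 ± 0.254. The call held in T31A (adjusted p = 0.0296 with an estimated correlation) and was lost in K36A and efs, with adjusted p = 0.132 and 0.0754 with an estimated correlation. Of 9 evening genes, 5 rose and 1 fell in T31A, 4 rose in K36A and 5 rose in efs, with 6, 4 and 5 called when adjusted over the list alone. ELF4 (AT2G40080) rose from 155 ± 20.2 to 223 ± 7.13, 287 ± 21.5 and 208 ± 12.2, and LUX (AT3G46640) from 54.1 ± 4.01 to 72.8 ± 3.35, 65.5 ± 2.98 and 71.3 ± 2.03. PRR5 (AT5G24470) fell in T31A, from 88.5 ± 10.1 to 66.6 ± 5.27. The evening list was called in T31A (camera adjusted p = 0.0477) and not in K36A (0.352) or efs (0.0769). That T31A call was lost with an estimated correlation (adjusted p = 0.251), with median-of-ratios factors (0.0666), and without Col replicate 2 (0.118), T31A replicate 1 (0.0578) or T31A replicate 2 (0.0802). In efs it was gained with quantile normalization (0.0495) and without Col replicate 3 (0.0497). The labels give no harvest time.

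Genes of photosynthesis and chlorophyll synthesis, which mark green tissue, fell in part in each mutant. Of 26 tested, 11 fell and 1 rose in T31A, 14 fell in K36A and 21 fell in efs, with 13, 16 and 21 called when adjusted over the list alone. The list also holds the carotenoid isomerase gene CRTISO, which was among the largest falls in K36A and efs. The median log2 difference of the list was -0.143, -0.259 and -0.455 in T31A, K36A and efs, and the mean -0.252, -0.356 and -0.722. LHCB2.1 (AT2G05100), a light-harvesting protein, fell from 2768 ± 131 to 1680 ± 43.1, 1828 ± 20.9 and 1155 ± 7.29 TPM. GLK2 (AT5G44190), a regulator of chloroplast genes, fell from 150.4 ± 7.55 to 60.6 ± 2.87, 105 ± 8.18 and 32 ± 1.72, and GLK1 (AT2G20570) from 140.1 ± 22.1 to 89.1 ± 3.88 in T31A and 28.7 ± 1.39 in efs. PORB (AT4G27440) rose in T31A, from 935 ± 109 to 1205 ± 71.2. Tested as a list, these genes had a camera adjusted p of 4.1e-06, 6.2e-12 and 1.0e-12 in T31A, K36A and efs. The T31A call was lost, with adjusted p = 0.0689 with an estimated correlation, and the others held. Root markers, which mark another tissue, moved the opposite way to this group in K36A, where 10 of 18 rose and none fell. Genes of the LHCB1 and RBCS families are near-identical copies and uncertain one by one.

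Touch-induced genes, which also respond to wounding and handling, rose in each mutant. Of 14 tested, 10 rose and none fell in T31A, in K36A and in efs, and 11 were called in each when adjusted over the list alone. TCH4 rose from 34.5 ± 5.2 to 239 ± 3.09, 101 ± 2.45 and 723 ± 30.7. The calmodulin-like TCH2 (AT5G37770) rose by 1.36 (SE 0.07), 0.84 (SE 0.07) and 1.53 (SE 0.07) log2 units and the transcription factor ERF6 (AT4G17490) by 1.04 (SE 0.11), 0.76 (SE 0.11) and 1.53 (SE 0.11), in the order T31A, K36A and efs. The list had a camera adjusted p of 4.9e-07, 6.8e-05 and 2.7e-05, and the 3 calls held with an estimated correlation (adjusted p = 0.00984, 0.02 and 0.0224). TCH4 and its relatives also act in cell wall growth, so a place on this list does not set the stimulus.

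Salicylic acid and immune response genes rose in part in T31A and K36A, and immune receptor genes fell in part in K36A and efs. Of 21 salicylic acid and immune response genes, 14 were tested, of which 6 rose in T31A, 5 rose in K36A, and 4 rose and 2 fell in efs (adjusted over the list alone 8, 6 and 6). PR1 (AT2G14610) and PR2 (AT3G57260) were too low to be tested, with highest genotype means of 0.166 TPM in Col and 0.232 in T31A. ICS1 (AT1G74710) rose in T31A (limma adjusted p = 0.0152), was not called in K36A (0.673) and fell in efs (0.009). CBP60G (AT5G26920) was at 1.21 ± 0.131 in Col and rose to 7.61 ± 0.596 in T31A. PBS3 (AT5G13320) was at 0.498 ± 0.0575 and rose to 2.39 ± 0.30 in T31A and 2.98 ± 0.466 in K36A, and WRKY70 (AT3G56400) rose from 2.97 ± 0.49 to 9.34 ± 0.612 in K36A and 9.93 ± 0.986 in efs. The list was called in T31A (camera adjusted p = 0.00229) and in K36A (0.0153) and not in efs (0.877), and the K36A call was lost (adjusted p = 0.0938 with an estimated correlation). Of 15 NLR immune receptor genes, 2 rose and 4 fell in T31A, 2 rose and 5 fell in K36A, and 1 rose and 8 fell in efs (adjusted over the list alone 6, 8 and 9). LAZ5 (AT5G44870) fell from 20.2 ± 1.79 to 16 ± 1.2, 14 ± 1.45 and 3.41 ± 0.324, SNC1 (AT4G16890) from 87.8 ± 5.17 to 65 ± 3.39 in T31A and 41.2 ± 3.55 in efs, and ZAR1 (AT3G50950) rose from 33 ± 2.04 to 46 ± 3.93 in K36A and 53.6 ± 2.38 in efs. The list was called lower in K36A (0.00753) and efs (2.4e-04) and not in T31A (0.241). Both calls were lost with an estimated correlation (adjusted p = 0.449 and 0.371), and the K36A call also with the length and GC trend removed (0.299). NLR genes lie in clusters of similar copies.

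Of the genes of jasmonate synthesis and response, more fell than rose in T31A and K36A. Of 12 tested, 7 fell and 1 rose in T31A, 6 fell and 2 rose in K36A, and 6 fell and 5 rose in efs (adjusted over the list alone 8, 9 and 11). AOC2 (AT3G25770), an allene oxide cyclase, fell from 354 ± 58.1 to 199 ± 12.3, 174 ± 8.84 and 153 ± 8.25, and LOX2 (AT3G45140) from 92.2 ± 10.8 to 51.8 ± 3.07, 66.8 ± 0.746 and 27.5 ± 1.59. VSP1 (AT5G24780), a jasmonate-induced storage protein, rose from 13.6 ± 1.04 to 38 ± 1.8 in K36A and 31.2 ± 2.51 in efs. The camera adjusted p was 0.00229 in T31A, 0.0034 in K36A and 0.103 in efs, and both calls were lost (adjusted p = 0.184 and 0.189 with an estimated correlation). In efs the median of the list differed in sign from its mean and its test.

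Of the genes of the abscisic acid, drought and cold response, more fell than rose in each mutant. Of 21 tested, 6 fell in T31A, 8 fell and 3 rose in K36A, and 16 fell and 3 rose in efs (adjusted over the list alone 6, 14 and 20). RD29A (AT5G52310) was at 33.3 ± 3.23 in Col and 32.2 ± 0.63 in T31A and fell to 16.1 ± 1.31 and 13.4 ± 1.4 in K36A and efs. P5CS1 (AT2G39800), of proline synthesis, fell from 42.8 ± 1.93 to 22.2 ± 2.11, 28 ± 2.31 and 15.4 ± 0.81, and COR15B (AT2G42530) rose to 49.6 ± 0.384 in K36A and fell to 13.2 ± 0.352 in efs from 36.7 ± 3.66. By camera, the adjusted p was 0.021, 0.00986 and 1.4e-06. The T31A and K36A calls were lost (adjusted p = 0.146 and 0.132 with an estimated correlation), and the T31A call also without Col replicate 2 (0.0707) or T31A replicate 1 (0.0542). Of 15 heat shock genes, 9 fell and 1 rose in T31A, 5 fell and 4 rose in K36A, and 8 fell and 7 rose in efs (adjusted over the list alone 11, 10 and 15). HSP90.1 (AT5G52640) fell from 60.0 ± 7.95 to 25.4 ± 2.02 in T31A and 22.7 ± 0.339 in efs, and HSFB2A (AT5G62020) from 12.1 ± 1.02 to 4.3 ± 0.149 and 3.12 ± 1.1. The list was called in T31A, also with an estimated correlation (adjusted p = 2.1e-05 and 0.0296), and not in K36A (0.224), where its median and mean differed in sign, or efs (0.145).

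Of the brassinosteroid and growth genes, more fell than rose in T31A and K36A. Of 18 tested, 8 fell and 2 rose in T31A, 8 fell in K36A, and 8 fell and 4 rose in efs (adjusted over the list alone 10, 8 and 12). The expansins EXPA1 (AT1G69530) and EXPA8 (AT2G40610), which loosen cell walls, fell from 309.6 ± 28.7 and 227 ± 25.5 to 93 ± 5.13 and 72.1 ± 5.56 in T31A, 138 ± 11.5 and 117 ± 14.5 in K36A, and 92.7 ± 3.43 and 40.0 ± 3.7 in efs. Tested as a list, these genes had a camera adjusted p of 0.0034, 1.9e-07 and 0.0769, and the T31A call was lost (adjusted p = 0.113 with an estimated correlation). Without efs replicate 2 the list was called in efs as well (0.0432). Root markers, which follow the amount of root tissue as well as its state, differed between T31A and K36A. Of 18 tested, 7 fell and 1 rose in T31A, 10 rose in K36A, and 4 rose and 2 fell in efs (adjusted over the list alone 8, 13 and 5). The root hair expansin EXPA7 (AT1G12560) was at 10.7 ± 0.474 in Col, 6.59 ± 1.06 in T31A and 21.1 ± 2.88 in K36A, and the iron transporter IRT1 (AT4G19690) at 11.7 ± 0.065, 5.69 ± 1.21 and 20.5 ± 1.94, all 4 changes called. The list had a camera adjusted p of 0.00563 in T31A, 0.00122 in K36A and 0.818 in efs, and both calls were lost (adjusted p = 0.251 and 0.189 with an estimated correlation). In the direct contrast of T31A and K36A, 14 of 18 were lower in T31A and none higher (camera adjusted p = 1.5e-06, and adjusted p = 0.133 with an estimated correlation).

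More seed maturation genes rose than fell in each mutant, among them storage protein genes with a low level in Col. Of 14 tested, 10 rose and 1 fell in T31A, 7 rose in K36A, and 8 rose and 1 fell in efs (adjusted over the list alone 12, 9 and 12). Besides SESA5, CRC, CRA1 and EM1, the albumins SESA1 (AT4G27140), SESA2 (AT4G27150) and SESA3 (AT4G27160) were listed at 0 in the 3 Col libraries and at 1.5 ± 0.344, 3.68 ± 1.15 and 0.686 ± 0.38 TPM in T31A. ABI5 (AT2G36270), a regulator of seed genes, rose from 6.43 ± 0.245 to 10.7 ± 0.752 in T31A and 10.6 ± 0.915 in K36A, and the oleosin OLEO2 (AT5G40420) fell in T31A (log2 difference -0.39 (SE 0.09, adjusted p = 0.00568)). The camera adjusted p was 2.4e-06, 0.0034 and 0.0208. The call held in T31A (adjusted p = 0.044 with an estimated correlation) and was lost in K36A and efs (adjusted p = 0.169 and 0.335 with an estimated correlation), in efs also without Col replicate 1 (0.0784). Storage albumins and cruciferins have similar copies.

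H3.1 genes, which are transcribed in dividing cells, rose in T31A and K36A. Of 5 tested, 4 rose in T31A and 4 in K36A, and none was called in efs with TPM as deposited (adjusted over the list alone 5, 4 and 0). HTR13 (AT5G10390) rose from 25.9 ± 4.72 to 58.7 ± 1.43 and 39.3 ± 7.38 and HTR9 (AT5G10400) from 58.6 ± 9.13 to 95.2 ± 2.37 and 77.3 ± 4.94, with 27 ± 2.06 and 53.1 ± 1.75 in efs. Limma called 0 of 5 in efs, with 1 past an unadjusted p of 0.05. With median-of-ratios factors, HTR1 (AT5G65360) and HTR2 (AT1G09200) were lower in efs than in Col (adjusted p = 0.0328 and 0.0495). By camera, the adjusted p was 1.0e-04, 0.00986 and 0.332, and both calls were lost (adjusted p = 0.0551 and 0.17 with an estimated correlation). The K36A call was also lost without Col replicate 1 (0.0513). DNA damage response genes were called in T31A, where 5 of 10 rose and none fell, against 3 risen in K36A and 3 risen and 1 fallen in efs (adjusted over the list alone 7, 3 and 4, and camera adjusted p = 0.00365, 0.428 and 0.866). TSO2 (AT3G27060), a ribonucleotide reductase subunit, rose from 58.5 ± 6.4 to 95.8 ± 5.68 in T31A and fell to 32.6 ± 4.24 in efs. The T31A call of the DNA damage list was lost (adjusted p = 0.184 with an estimated correlation).

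Of the flavonoid genes, some rose in K36A, where root markers rose as well (10 of 18). Of 9 tested, 4 rose in K36A, and 3 rose and 3 fell in efs. In T31A limma called 0 of 9, with 1 past an unadjusted p of 0.05. Adjusted over the list alone, 0 were called in T31A, 6 in K36A and 6 in efs. CHS (AT5G13930), chalcone synthase, rose from 57.5 ± 13.4 to 163 ± 21 in K36A and 126 ± 4.62 in efs and was at 68.6 ± 6.43 in T31A, where without Col replicate 1 it was called (adjusted p = 0.0029). Tested as a list, these genes had a camera adjusted p of 0.998, 0.0034 and 0.65, and the K36A call was lost (adjusted p = 0.17 with an estimated correlation). The median, mean and test of the list differed in sign in T31A and efs.

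The remaining lists were called in no mutant. Of 13 floral promoters, 12 were listed and only 5 passed the TPM filter and were tested. Of these 5, 3 rose and 2 fell in T31A, 3 rose and 1 fell in K36A, and 3 rose in efs (adjusted over the list alone 5, 4 and 3, and camera adjusted p = 0.721, 0.372 and 0.167). FT (AT1G65480) was not tested, at 0.0693 ± 0.085 TPM in Col, 0.0502 ± 0.0869 in T31A, 0.765 ± 0.199 in K36A and 0.7415 ± 0.13 in efs. AGL19 (AT4G22950), not tested either, was at 0.391 ± 0.0841 in Col, 0.272 ± 0.0247 in T31A, 0.149 ± 0.0136 in K36A and 0.794 ± 0.229 in efs. SOC1 (AT2G45660) rose from 14 ± 1.92 to 21.1 ± 0.174, 25.4 ± 2.03 and 19.7 ± 1.5 TPM and SPL3 (AT2G33810) from 10.6 ± 1.48 to 13.4 ± 1.29, 17.2 ± 0.301 and 17.9 ± 1.33. Of 3 tested floral organ genes, 1 fell in T31A, 1 rose in K36A, and 2 rose and 1 fell in efs (adjusted over the list alone 1, 2 and 3, and camera adjusted p = 0.59, 0.475 and 0.627). SEP3 (AT1G24260) rose from 11.7 ± 0.84 to 34 ± 3.28 in K36A and 24.5 ± 1.71 in efs. Of 17 genes for H3K36 methylation, its readers and H3 chaperones, 1 rose in T31A, 4 rose in K36A, and 6 rose and 1 fell in efs (adjusted over the list alone 1, 3 and 6, and camera adjusted p = 0.585, 0.726 and 0.516). SDG26 (AT1G76710), another H3K36 methyltransferase, rose from 10.4 ± 0.463 to 15 ± 1.13 in efs. Of the 4 calls of this list in K36A, 3 depended on the setting. SDG26 was lost with quantile normalization (adjusted p = 0.0573), on the 2 groups alone (0.0547) and without K36A replicate 3 (0.0516). MSI1 (AT5G58230) was lost with median-of-ratios factors (0.0638), on the 2 groups alone (0.0572) and with voom (0.0507). NRP1 (AT1G74560) was lost under 11 alternatives, among them median-of-ratios factors (0.457), quantile normalization (0.222) and leaving out Col replicate 1 (0.105) or 3 (0.0543) or K36A replicate 1 (0.102), 2 (0.0657) or 3 (0.112). Of 11 hypoxia genes, 2 rose and 2 fell in T31A, 1 rose and 1 fell in K36A, and 6 rose and 1 fell in efs (adjusted over the list alone 4, 2 and 7, and camera adjusted p = 0.785, 0.937 and 0.22). Of 7 reference genes, 1 fell in T31A, 1 rose in K36A, and 1 rose and 1 fell in efs (adjusted over the list alone 1, 1 and 2, and camera adjusted p = 0.692, 0.689 and 0.65). The median and mean or test of the reference list differed in sign in K36A and efs. In efs, ACT2 (AT3G18780) was at 739 ± 52.8 against 579.6 ± 54.9 and GAPC2 (AT1G13440) at 378 ± 17.7 against 619.8 ± 83.9. Of the 23 lists, 15 were called in T31A, 14 in K36A and 8 in efs, and 5, 5 and 3 of them with an estimated correlation.

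**Figure D4:**
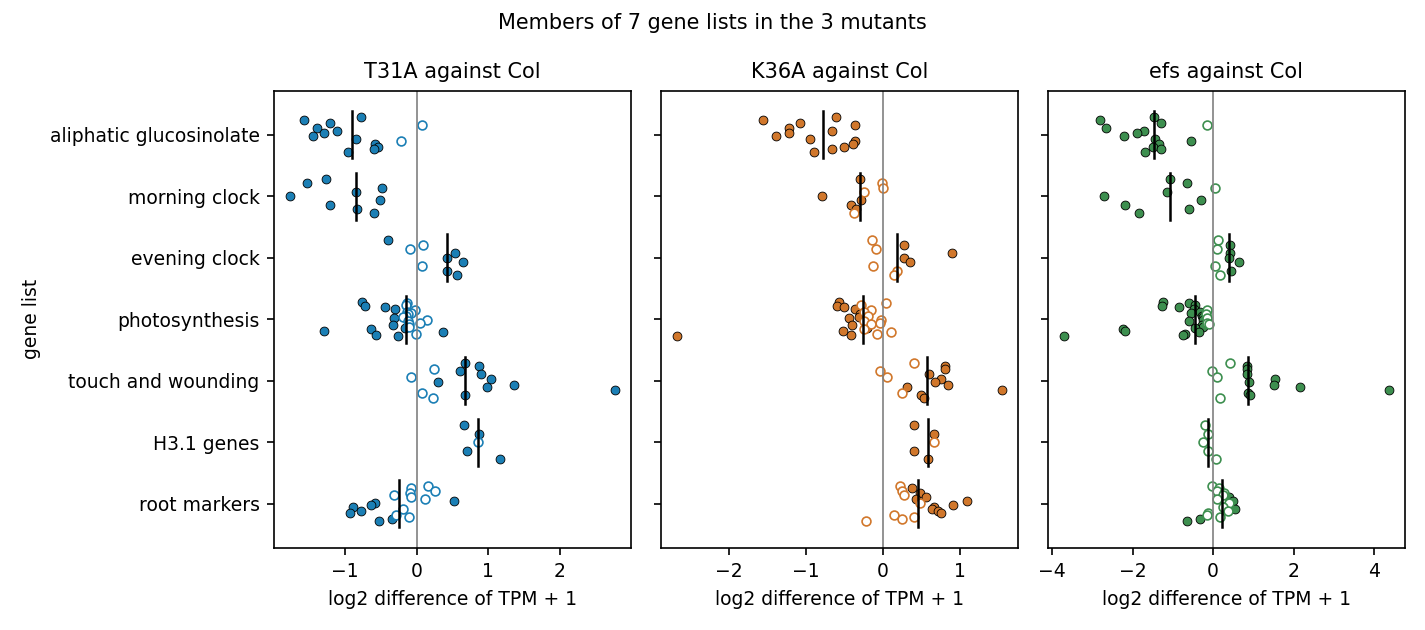
Log2 differences from Col on the TPM + 1 scale (x axis, own range per panel) of the members of 7 gene lists (y axis) in T31A, K36A and efs. Each point is a gene, filled where its adjusted p was under 0.05, and the vertical bar is the median of the list. Glucosinolate genes lie left of 0 in the 3 panels except MAM3 in T31A, with 11, 13 and 12 called of 13.

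The direct contrast of T31A and K36A compares the substitutions on what the labels give as one background. Each substitution sits on its own added copy, so other differences between the copies or the lines cannot be told apart from the substitution. Of 19984 genes, 5643 were called, 2045 higher in T31A and 3598 higher in K36A, and 476 differed by at least 2-fold (133 higher and 343 lower in T31A). SESA5, CYP71A12, AT5G60030, GLP9 and MAF1 were higher in T31A, with log2 differences of 4.24 (SE 0.18), 3.72 (SE 0.11), 2.57 (SE 0.15), 2.48 (SE 0.13) and 2.43 (SE 0.09). Higher in K36A were the defensin-like AT3G59930 (22.4 ± 5.12 against 1.85 ± 0.399 TPM), AT5G42530 (55 ± 6.59 against 8.46 ± 1.83), AT4G19430, the lipid-recognition protein AT2G16005 (56.8 ± 3.54 against 10.8 ± 1.47) and HSP18.2 (AT5G59720) (19.7 ± 1.4 against 3.88 ± 0.625). Of the called genes, 36.2% were higher in T31A, 46.8% with median-of-ratios factors and 50.3% with quantile normalization.

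Between T31A and efs, 7822 genes were called, 3337 higher and 4485 lower in T31A, with 934 of at least 2-fold (418 higher and 516 lower). Higher in T31A were CYP71A12 (41.6 ± 1.03 against 0.45 ± 0.179), SESA5, CRTISO (27.8 ± 0.884 against 1.65 ± 0.0735), GLP9 and AT2G15029. Lower were HTR8, MIOX2 (16.9 ± 0.537 against 218 ± 8.88), AT2G16005, RLP19 and XTH15 (AT4G14130) (17.7 ± 1.54 against 134 ± 3.37), which overlaps AT4G14120. Between K36A and efs, 7472 genes were called, 3999 higher and 3473 lower in K36A, with 838 of at least 2-fold (521 higher and 317 lower). Higher in K36A were SPX1 (AT5G20150), a sensor of phosphate status (96.4 ± 12 against 14.2 ± 1.35), AT1G80130, AT1G47395, AT2G15029 and AT2G30766, which overlaps 2 annotated genes. Lower were ASN1 (AT3G47340), the asparagine synthetase (62.5 ± 0.212 against 597 ± 5.54), MIOX2, PHI-1, HTR8 and ERD5 (75.1 ± 10.9 against 545 ± 43.1). The share of calls higher in T31A than in efs was 42.7% with TPM as deposited, 51.9% with median-of-ratios factors and 50.8% with quantile normalization, and the share higher in K36A than in efs 53.5%, 53.8% and 49.6%.

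Changes against Col overlapped between the mutants. Between T31A and K36A, 1662 genes were higher and 787 lower in both, where independent lists of these sizes would share 707 and 197.5. Between T31A and efs, 2140 were higher and 1225 lower in both (982.2 and 385.4 for independent lists), and between K36A and efs, 2771 and 1070 (1418.3 and 309). The balance depended on the scaling: with median-of-ratios factors the 3 pairs shared 938 higher and 1383 lower, 1452 and 1796, and 1515 and 1885 genes, and with quantile normalization 950 and 1286, 1533 and 1637, and 1507 and 1740. In all 3 mutants, 1248 genes were higher and 601 lower with TPM as deposited. The 3 comparisons share the Col libraries: simulated unchanged groups gave a mean of at most 0.04 shared calls, with r = 0.5 across genes. With no group changed, hardly any gene passes the adjusted p, so this low count was fixed by the setting. It does not give the number of shared calls that shared controls add where many genes change. The simulated spread was independent between genes, so the simulations do not cover trends of a whole library, such as that over length in Col replicate 1. The observed r of fold changes across genes was 0.464, 0.512 and 0.528, close to the 0.5 of the simulations, so r by itself does not set the overlap apart from shared controls. The covariance was 0.05797, 0.09478 and 0.09483, against 0.00724, 0.00724 and 0.00725 in the simulations. With 3 Col libraries the controls were not split, so the part of the overlap that comes from shared controls was not removed.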

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

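Of the tests below, those on the neighbours of HTR5, the order of clock genes and the length trend of Col replicate 1 were chosen only after the result was seen, while those with the length and GC trend removed from process terms and the splits of libraries were written down before. The genes in this paragraph and the next changed in opposite directions from Col in 2 mutants, and the mutants also differed in their direct contrast. This held for 325 genes between T31A and K36A, 463 between T31A and efs, and 365 between K36A and efs, of 19984 tested. These are all the genes called in opposite directions against Col, so the direct contrast removed none of them and adds no separate support. In the same pairs, far more genes, 2449, 3365 and 3841, were called in the same direction. T31A minus K36A was -3.03 (SE 0.19) log2 units for AT3G59930, -2.58 (SE 0.18) for AT5G42530, -2.29 (SE 0.10) for AT2G16005, -2.09 (SE 0.11) for HSP18.2, -1.73 (SE 0.08) for VSP1, -1.72 (SE 0.09) for SEP3, -1.70 (SE 0.11) for IRT1, -1.55 (SE 0.11) for EXPA7 and -1.54 (SE 0.14) for EXPA18 (AT1G62980), with 3 libraries on each side.

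T31A minus efs was 4.88 (SE 0.11) log2 units for CYP71A12, -3.68 (SE 0.14) for HTR8, -3.18 (SE 0.10) for AT2G16005, -2.66 (SE 0.18) for AT5G42530, 2.03 (SE 0.14) for PCO2 (AT5G39890), -1.93 (SE 0.19) for AT3G59930, 1.53 (SE 0.10) for TSO2, -1.52 (SE 0.11) for HSP18.2, -1.45 (SE 0.08) for VSP1, 1.27 (SE 0.08) for EXPA5 (AT3G29030), -1.27 (SE 0.09) for SEP3, 1.25 (SE 0.10) for ADR1 (AT1G33560) and -1.09 (SE 0.11) for XERO2 (AT3G50970). K36A minus efs was -3.35 (SE 0.14) for HTR8, -3.24 (SE 0.06) for ASN1, 2.94 (SE 0.16) for AT1G80130, 2.74 (SE 0.11) for AT2G30766, 2.67 (SE 0.10) for AT1G47395, 1.83 (SE 0.09) for COR15B, 1.2 (SE 0.11) for HAI1 (AT5G59220), 1.19 (SE 0.10) for TSO2, 1.16 (SE 0.15) for MYB12 (AT2G47460), 1.06 (SE 0.11) for F3H (AT3G51240) and -1.03 (SE 0.11) for ETR2 (AT3G23150). The fall of SEP3 in T31A against Col (adjusted p = 0.0405) was lost without Col replicate 1 (0.0873) or 3 (0.0982), without T31A replicate 1 (0.131), 2 (0.0914) or 3 (0.059), with a pseudocount of 5 (0.0651), and on the 2 groups alone (0.0779). The rise of TSO2 in K36A against Col (adjusted p = 0.0119) was lost with median-of-ratios factors (0.0726) and with quantile normalization (0.0542).

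The 2 annotated genes next to HTR5 on one side rose with it: AT4G40042 was at 12.9 ± 4.38 TPM in Col, 47.3 ± 8.05 in T31A, 57.4 ± 14.0 in K36A and 15.4 ± 3.22 in efs, and AT4G40045 at 44.5 ± 2.13, 93.0 ± 6.43, 69.0 ± 6.02 and 39.2 ± 1.66. Rises on that side were not confined to these genes or to T31A and K36A. Farther out, log2 differences in T31A, K36A and efs were 0.48, 0.72 and 1.38 for AT4G40070, all called. They were 1.02, 0.60 (not called) and 0.83 for AT4G40063. Between them and AT4G40045, AT4G40050 had 0.25, 0.04 (not called) and 0.19, and HB16 (AT4G40060) fell in T31A (-0.26). A constant share of HTR5 reads counted in AT4G40042 was argued against, since the log2 fold of this gene against Col exceeded that of HTR5 by 0.84 (SE 0.24) in T31A and 1.24 (SE 0.28) in K36A. For AT4G40045 the same difference was 0.05 (SE 0.15) in T31A and -0.23 (SE 0.15) in K36A, so read spill and a rise of the gene itself cannot be told apart. An added HTR5 copy that carries sequence beside the gene stays open: 4 of 4 pairs of gene and genotype were called higher against Col and against efs, but this is the observation that raised the question, and the labels do not give the extent of the transgene.

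The fold changes against Col of 4 clock genes rose in the order of their known peak times, PRR9, PRR7, PRR5 and TOC1, in 3 of 3 comparisons, the observation from which both explanations below were drawn. In T31A they were -1.76, -0.51, -0.40 and 0.08, in K36A -0.79, -0.29, -0.14 and 0.28, and in efs -2.71, -0.31, 0.12 and 0.42 log2 units. The values of PRR7 and PRR5 in T31A lay close together. The 4 genes were picked from 9 tested morning and 9 tested evening genes after the values were seen. An order over the other clock genes was not tested, and CCA1, another morning gene, fell less than PRR9 in each mutant. Mutant seedlings harvested later in the day than Col could give this order, and so could genotypes that shift the clock itself. These cannot be told apart, as the labels give a harvest time for 0 libraries. Genes that follow the clock, such as those of photosynthesis and growth, share this limit.

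The difference from Col between short and long transcripts was 0.101 (SE 0.116) log2 units in T31A, 0.175 (SE 0.114) in K36A and 0.107 (SE 0.108) in efs, all 3 within 2 SE of 0. Without Col replicate 1, the library with the strongest length trend, it was -0.003 (SE 0.066), 0.072 (SE 0.062) and 0.003 (SE 0.051), which says nothing of a cause. Trends over length and GC content as the whole cause of the rise of nucleosome assembly genes were argued against, as the term stayed called with the trend removed (adjusted p = 4.2e-11 in T31A and 8.4e-06 in K36A), and so were they for translation genes in T31A (1.5e-05), although without the trend removed these calls were lost with an estimated correlation (adjusted p = 0.932, 0.995 and 0.999). For translation genes in K36A and efs the trend removal ended the call (adjusted p = 0.36 and 0.15): the median log2 difference went from 0.25 (quartiles 0.10 and 0.35) to 0.17 (0.03 and 0.26) in K36A and from 0.24 (0.11 and 0.39) to 0.20 (0.06 and 0.30) in efs, nearer the medians of all genes, 0.11 and 0.12. These 2 calls ended too without Col replicate 1 (0.16 and 0.203) and with an estimated correlation (adjusted p = 0.995 and 0.983), and the medians were 0.15 and 0.14 with median-of-ratios factors.

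With 3 libraries against 3, 10 splits of the 6 libraries exist, too few for a share under 0.05. The real split, 1 of 10, called 5347 genes in T31A, 6296 in K36A and 9746 in efs against Col, 5643 between T31A and K36A, 7822 between T31A and efs and 7472 between K36A and efs, and the highest other split called 0 in each. Every other split mixes the 2 genotypes, so a real difference widens its spread and lowers its calls. The 0 is therefore not a level for unchanged groups. For gene lists, 15 were called in T31A and 14 in K36A against at most 9 in another split, with 1 of 10 splits as large in each, and 8 in efs against 8, with 2 of 10 as large.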

How the results depend on the processing

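Voom, removal of the length and GC trend, and the fits without Col replicate 1 as a library of its own kind were chosen after seeing the data, and the other alternatives before. Of 322 named gene comparisons, 310 were called, 290 of these kept their direction and call under each alternative chosen before the data were seen that tested the gene, and 289 with those added later as well. Most named genes were picked for a small p or a large change, so this does not carry over to all genes. Over all genes, 4641 of the 5347 calls in T31A were also called with median-of-ratios factors, 4545 of the 6296 in K36A and 7735 of the 9746 in efs. The filter on a mean TPM of at least 5 left 274 of the 322, and the fold of at least 2 was applied to counts and overlaps and not to single genes. Of 37 list calls, 36 were kept under the 3 scalings, 33 with any 1 library left out, 37 with voom, 33 with the trend removed, 36 with fry and 13 with an estimated correlation. No call of a named gene or list turned its direction, while the balance of calls did: in T31A, K36A and efs 58.5%, 71.7% and 64.4% were higher with TPM as deposited, and 44.6%, 47.7% and 47.9% with median-of-ratios factors. Counts of genes stayed within 1.5 times under each alternative except 2. At a fold of at least 2, which can only lower a count, 401, 405 and 1197 genes were called against Col in T31A, K36A and efs, and 476, 934 and 838 between T31A and K36A, T31A and efs, and K36A and efs. At that fold, 100, 207 and 148 genes changed the same way in T31A and K36A, in T31A and efs, and in K36A and efs. Fitted on only the 2 groups compared, K36A against Col called 4137 genes, with fewer libraries behind the spread. By direction, the K36A counts moved under the scalings: 2766 higher and 3031 lower with median-of-ratios factors, 2627 and 2971 with quantile normalization, 2801 and 3221 with voom, and 2953 and 1184 on the 2 groups alone. The median log2 difference of all genes went from 0.04, 0.10 and 0.12 in T31A, K36A and efs to -0.01, 0.00 and 0.02 with median-of-ratios factors. Lists called with an estimated correlation were 5 in T31A, 5 in K36A and 3 in efs, and with fry, which compares a list with no other genes, 18 in efs. The replicate numbers did not pair the libraries as a whole: in 18 pairs of libraries with the same number, correlations of residuals ran from -0.24 to 0.36, 6 were over 0.1, and 5 of 12 libraries correlated best with their own number. For replicate 3, residuals correlated at 0.36 between Col and K36A, 0.22 between Col and efs and 0.25 between K36A and efs. With a replicate block the counts were 5316, 6252, 9717, 5549, 7750 and 7456, and the evening clock call in T31A was lost (adjusted p = 0.056), as was NRP1 in K36A (0.054). Where a call moved and no construction is named, the cause was not tested. Depth limits genes with low TPM: 1390 listed genes had under 10 recovered reads over the 12 libraries.

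Among the calls of named genes that ended without 1 library were AGL42 (AT5G62165) in T31A without Col replicate 1 (adjusted p = 0.0598), T31A replicate 1 (0.0662) or T31A replicate 2 (0.0583), ADR1-L2 (AT5G04720) in T31A without Col replicate 2 (0.0685), T31A replicate 2 (0.0827) or T31A replicate 3 (0.0583), AGL24 (AT4G24540) in K36A without Col replicate 2 (0.0615) or K36A replicate 3 (0.0516), BOA (AT5G59570) in K36A without Col replicate 2 (0.0533) or K36A replicate 2 (0.0509), and PR5 (AT1G75040) in efs without Col replicate 1 (0.0564) or efs replicate 2 (0.0612). Further ones were SPL4 (AT1G53160) in K36A without Col replicate 3 (0.0648), K36A replicate 2 (0.0883) or K36A replicate 3 (0.0551), PDC1 (AT4G33070) in K36A without Col replicate 2 (0.1), K36A replicate 1 (0.0937) or K36A replicate 3 (0.0798), UBQ10 (AT4G05320) in T31A without T31A replicate 1 (0.0768), SMR7 (AT3G27630) in efs without efs replicate 3 (0.064), and KU70 (AT1G16970) in efs without efs replicate 1 (0.0636) or 3 (0.0532). The rise of TSO2 in K36A was lost with median-of-ratios factors (0.0726) and quantile normalization (0.0542), and the rises of SPL4 and PDC1 in K36A with quantile normalization (0.106 and 0.134). With the trend removed, EFS was called higher in T31A and K36A (log2 difference 0.24 and 0.31, adjusted p = 0.0275 and 0.0058), and the MAF1 call in T31A ended (0.402). MAF3 was called higher in T31A with a pseudocount of 5 (0.0374), nuclear genes only (0.0499), the 2 groups alone (0.0455), voom (0.0436) and the trend removed (0.0179). HTR4 was called lower in efs without Col replicate 1 (-0.18, adjusted p = 0.0251), and the HTR5 call in efs ended with voom (0.151). MAF2 was called lower in efs with median-of-ratios factors (0.0451) and voom (0.0254). The seed list in efs was lost with a pseudocount of 5 (0.0593) and with the trend removed (0.0733), the H3.1 list in K36A with the trend removed (0.0758), and the immune receptor list in K36A with fry (0.169).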

Other observations

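The process terms below were tested after the data were seen, in 250 terms of 10 to 500 genes, and the trend removal applied to 2 of them was written down before its result. Of 50 genes of nucleosome assembly, 36 rose and 2 fell in T31A and 35 rose and 2 fell in K36A, with median log2 differences of 0.68 (quartiles 0.25 and 0.97) and 0.53 (0.27 and 0.89). The camera adjusted p was 8.7e-13 and 3.9e-08, with the trend removed 4.2e-11 and 8.4e-06, and without Col replicate 1 1.6e-12 and 1.4e-07. Both calls were lost with an estimated correlation (adjusted p = 0.932 and 0.995). In efs, 20 rose and 3 fell, with a median of 0.10 (-0.01 with median-of-ratios factors, and 0.12 for all genes with TPM as deposited) and an adjusted p of 0.718. Of 357 translation genes, 125 rose and 3 fell in T31A (median 0.24, adjusted p = 1.3e-07), and of 98 ribosome biogenesis genes 42 rose and 1 fell (0.30, 5.5e-06). These calls were kept without Col replicate 1 (0.00119 and 0.00926) and lost with an estimated correlation (adjusted p = 0.999 for each). In K36A and efs, ribosome biogenesis was called (0.00116 and 0.0063), a call that was lost with an estimated correlation (adjusted p = 0.995 and 0.983), without Col replicate 1 (0.334 and 0.157) and with the trend removed (0.451 and 0.105). The median log2 difference went from 0.29 (quartiles 0.18 and 0.37) to 0.20 (0.05 and 0.28) in K36A and from 0.31 (0.17 and 0.45) to 0.22 (0.10 and 0.35) in efs with the trend removed, where the medians of all genes were 0.11 and 0.12. With median-of-ratios factors it was 0.19 and 0.20.

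The calls in this paragraph were lost with an estimated correlation, with adjusted p = 0.983 in efs (0.611 for small GTPase signalling), 0.995 in K36A, and 0.996 between T31A and K36A. Genes of starch breakdown fell in efs, 10 of 10 (median -0.42, adjusted p = 9.8e-05), and in K36A, 5 of 10 (-0.18, and -0.28 with median-of-ratios factors, 8.2e-04). With the trend removed, the median of these genes was -0.38 in efs and -0.09 in K36A (camera adjusted p = 3.8e-05 and 0.0175). Genes of electron transport in photosystem I fell in efs, 11 of 15 (2.5e-05), and in K36A, 6 of 15 (0.00234). Genes of the response to far red light fell in K36A, 7 of 18 with 1 risen (4.0e-05), and in efs, 9 of 18 with 3 risen (0.0063). Cell wall organization genes rose in K36A, 15 of 20 with 1 fallen (median 0.57, 0.00734), and were lower in T31A than in K36A, 15 of 20 with 3 higher (-1.26, 0.0046). Root markers moved the same way in these contrasts, with 10 of 18 risen in K36A and 14 of 18 lower in T31A than in K36A. Small GTPase signalling genes rose in efs, 26 of 52 with 2 fallen (0.00738).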
